A study of Mus musculus with 2 samples.

How the data were processed

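Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on mouse embryonic stem cells with an antibody against Pwp1, a WD-repeat protein of the nucleus. Per the labels, the series holds 1 Pwp1 ChIP library and 1 input DNA library, the latter made from chromatin without immunoprecipitation. Per the labels' protocols, the E14.1 cells grew on gelatin in medium with 15% serum and 1000 units per ml of LIF, the cytokine that keeps mouse embryonic stem cells undifferentiated through Stat3. The processed data analysed here were the peak list of the ChIP library. No file of the input library was analysed here.

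The peak list deposited by the authors has 3 columns without a header, which hold the chromosome, the start and the end of each peak. It holds no score, fold over input, p-value, tag count or gene. The submitters' processing notes name CASAVA 1.4, Bowtie 0.12.7 and HOMER 4.3 and the mouse genome build mm9. Their roles and settings, the peak threshold, any filter and the use of the input in peak calling are not given in the sources used here. The sequencing depth is likewise unknown, so no value per peak carries a depth of its own. Starts were read as counted from 0, following the BED convention, and are printed counted from 1. No line had its start at or beyond its end, and 0 pairs of neighbouring peaks overlapped.

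No genome sequence or annotation of mm9 was used here. The gene table at hand was built on GRCm38, a later build, and on 6 of 21 chromosomes the last peak lay beyond the last gene of that table. Its genes were therefore not placed against the peaks. The comparisons planned before the data were examined that need genes or sequence were not made: the promoter share, the genomic location, the gene lists, the base composition and the motif matches. Whether a peak lies at Stat3, which the series title names, or at Pwp1 itself was not analysed here. Ranking peaks by strength was also not possible, because the list carries no value per peak, and peak width took its place. The rule for named items, fixed before the data were examined, then left the 3 widest peaks by position. All other regions named were chosen after their values were seen.

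From the positions, peak width, peak number per chromosome and the distance between peak centres were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Chromosome lengths of mm9 were not used, so density was computed over the span from the first to the last peak of a chromosome. This span is at most the length of the chromosome, so it can overstate density and cannot understate it. Densities have exact Poisson intervals and shares exact Clopper-Pearson intervals, both at 95%. These cover counting error only, since there is 1 ChIP library and no replicate. Every p-value below therefore compares parts of the genome within 1 peak list, not conditions.

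The number of peaks per chromosome was to be reported as counts where no genome of the build was at hand. The tests that follow were added after seeing the data. Peak centres were counted in 10 Mb windows lying wholly inside the span. The mean over each chromosome's windows was compared with the mean of as many windows drawn at random from all chromosomes, in a 2-sided permutation test with 100000 draws. A step in density along each autosome was located as the split of its 1 Mb bins, with at least 10 bins on either side, that gave the largest Poisson likelihood. Its p-value came from 10000 shuffles of blocks of 5 Mb, which keep the local unevenness of the counts. Peaks wider than 167 bp, the commonest width, were compared across each step with Fisher's exact test, 2-sided. All of these were adjusted by the Benjamini-Hochberg method over the chromosomes tested. Spacing was tested as planned, as the share of peaks with a neighbour within 10 kb against 1000 random placements inside the span of the same chromosome, and widths of peaks with and without such a neighbour were compared by 100000 permutations.

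The tests were tried on simulated data, 20 peak sets of even density with a 3-fold excess on chromosome 1, a 3-fold step on chromosome 6 and, for spacing, 150 added pairs. The excess, the step and the pairs were found in 20 of 20 sets each. The median error of the step position was 0 Mb. A step was called on 2 of 360 chromosomes without one, a spacing effect in 2 of 20 sets without added pairs, and a chromosome without an excess in 0. The sets without added pairs kept the step on chromosome 6, which can itself bring peaks closer together. The sets were otherwise even, had a larger chromosome excess than any seen below and were tested with fewer draws. Their step was also larger than the 2.36-fold one called on chromosome 5, and the added pairs were not matched to the spacing excess seen below. The sets do not show how often the tests find smaller effects, or err on counts as uneven as the real ones. Alternatives merged peaks within 1 kb, left out X and Y, and varied the windows, the blocks, the neighbour distance and the width limit.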

Results

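The binding sites of Pwp1 in mouse embryonic stem cells were mapped by ChIP-seq in 1 immunoprecipitated library, and 1 input DNA library was also sequenced. The question set by the series was where in the genome Pwp1 binds. The peak list held 5639 peaks on 21 chromosomes, of which 5615 lay on the autosomes, 17 on X and 7 on Y. Together they covered 947.8 kb. The peaks carried no height or p-value, so the comparisons below concern their position and width, and without replicates no value has a replicate error.

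The peaks as listed were narrow, with a median width of 167 bp and quartiles of 137 and 181 bp. How far the unknown settings of the peak calling fixed these widths could not be examined. The narrowest spanned 57 bp and the widest 976 bp. A width of exactly 167 bp was shared by 1719 peaks, or 30.5% of the list. A further 2118 peaks (37.6%) were narrower and 1802 (32.0%) were wider. The 3 widest peaks all lay at the start of chromosome 11, at 3,050,628 to 3,051,603 (976 bp), 3,031,795 to 3,032,436 (642 bp) and 3,099,454 to 3,100,068 (615 bp) of mm9. The gene content of these positions was not analysed here.

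**Figure D1:**
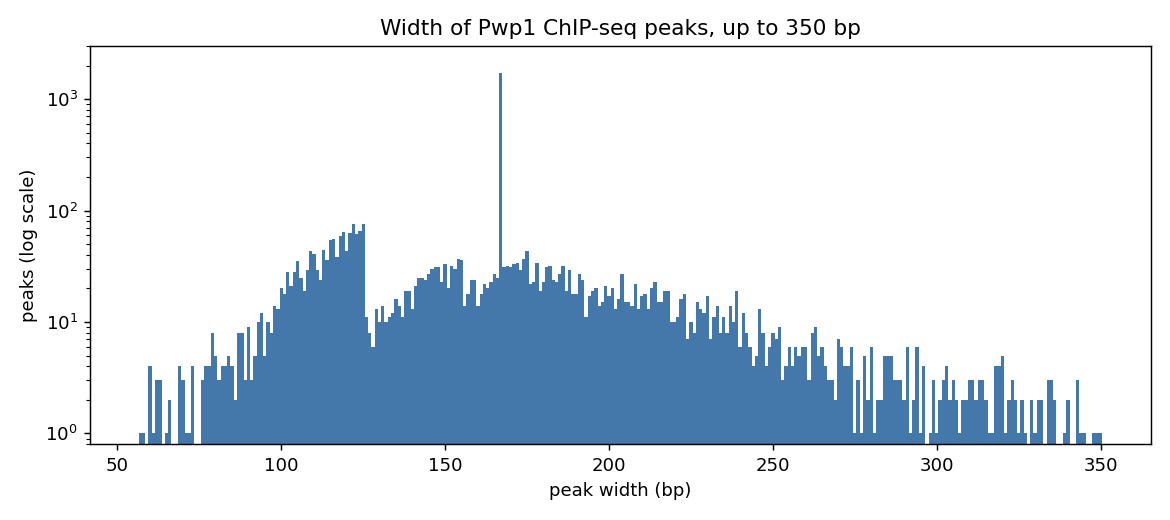
Number of peaks (vertical axis, log scale) at each peak width in bp (horizontal axis, to 350 bp), 1 bar per bp, in the 1 Pwp1 ChIP library. The bar at 167 bp holds 1719 peaks, and the count drops from 75 peaks at 125 bp to 11 at 126 bp.

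Peaks were spread unevenly over the chromosomes. Chromosomes 1, 11 and 14 held 799, 589 and 429 peaks, together 32.2% of the list. Chromosome 11 had the highest autosomal density, with 4.96 peaks per Mb of span (95% interval 4.57 to 5.38). Chromosome 1 had 4.13 peaks per Mb (3.85 to 4.43) and chromosome 14 had 3.97 (3.60 to 4.37). The other 16 autosomes ranged from 1.47 peaks per Mb on chromosome 3 to 2.55 on chromosome 6, with a median of 1.96. Relative to that median, density was 2.53-fold on chromosome 11, 2.10-fold on chromosome 1 and 2.02-fold on chromosome 14. Chromosome X, with 17 peaks, had 0.137 peaks per Mb (0.0798 to 0.219), 14.3-fold below the same median. The 7 peaks on Y lay between 1,595,061 and 2,859,245, too short a span for a density.

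The mean counts of the 10 Mb windows on chromosomes 1, 11, 14 and X differed from those of as many windows drawn from the whole genome. Single windows still overlapped between chromosomes. The draws treat neighbouring windows as unrelated, which the density steps below go against, so these p-values can be too small. The 18 windows of chromosome 1 held a mean of 40.8 peaks against 20.5 elsewhere, and the 11 windows of chromosome 11 held 47.9 against 20.8 (permutation test, adjusted p = 0.000133 for each, from the smallest p these draws can give). The 10 windows of chromosome 14 held 38.1 peaks against 21.3 (permutation test, adjusted p = 0.0119). The 12 windows of X held 1.08 against 23.2 (permutation test, adjusted p = 0.000133). The other 16 chromosomes tested did not pass, with adjusted p-values from 0.200 for chromosome 3 upward. In windows of 20 Mb the excess on chromosome 14 did not pass (permutation test, adjusted p = 0.257), and in windows of 5 Mb chromosome 3 also passed, with 7.45 peaks per window against 11.4 elsewhere (permutation test, adjusted p = 0.0469).

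**Figure D2:**
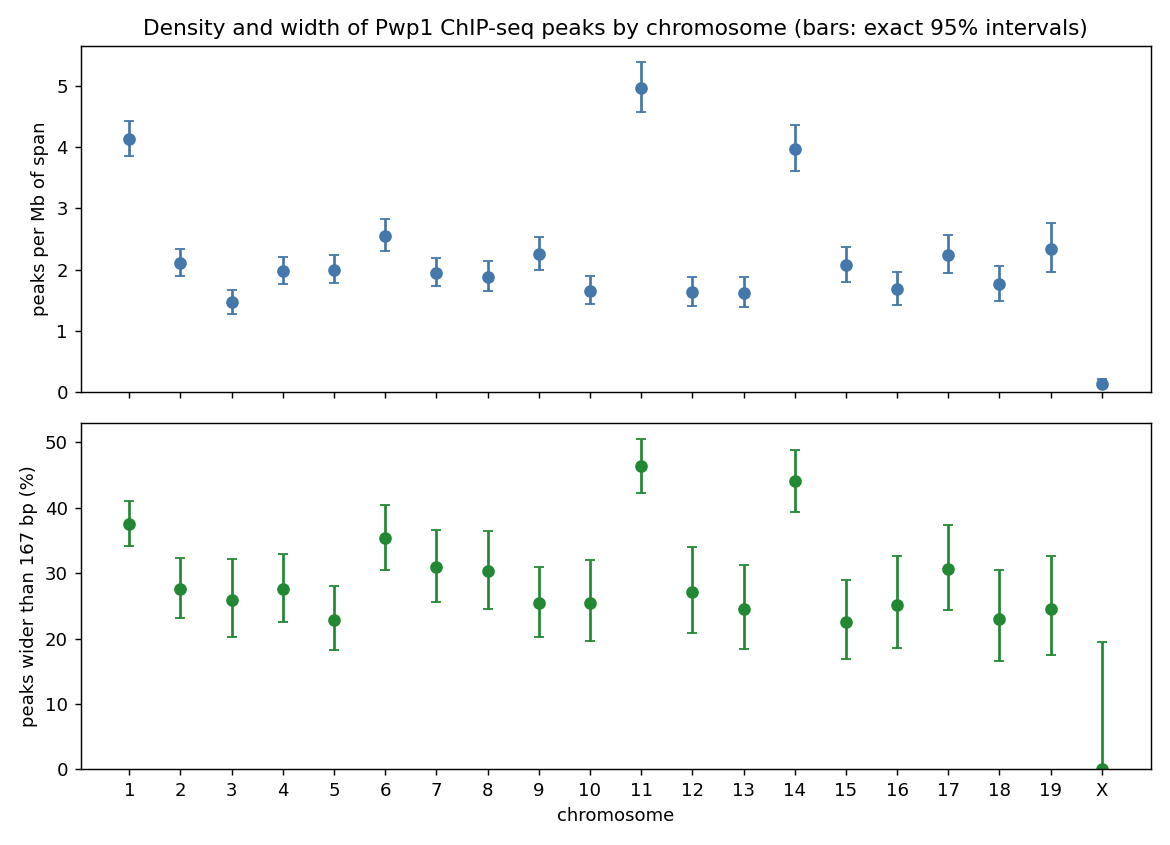
Peaks per Mb of the span between first and last peak (top) and percent of peaks wider than 167 bp (bottom) for each chromosome except Y, with points for the value in the 1 ChIP library and bars for exact 95% counting intervals. Chromosomes 1, 11 and 14 stand above the other autosomes in both panels, and X has 0.137 peaks per Mb and 0 wider peaks.

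Density rose towards the distal end of chromosomes 6 and 14. On chromosome 14 it was 1.84 peaks per Mb (1.51 to 2.21) from 8 to 69 Mb and 6.70 (5.97 to 7.49) from 69 to 115 Mb, a 3.65-fold step (block permutation test, adjusted p = 0.00095). On chromosome 6 it was 1.51 peaks per Mb (1.28 to 1.77) from 4 to 108 Mb and 5.12 (4.45 to 5.86) from 108 to 149 Mb, a 3.39-fold step (block permutation test, adjusted p = 0.00095). The distal parts of chromosomes 4 and 5 also held more peaks. Chromosome 4 went from 1.26 to 4.03 peaks per Mb at 117 Mb, and chromosome 5 from 1.37 to 3.24 at 103 Mb (block permutation tests, adjusted p = 0.0038 and 0.0109). Chromosomes 1 and 11 had no step that passed the test (block permutation tests, adjusted p = 0.245 and 0.362). The number of chromosomes with a step was 4 with 5 Mb blocks and 11 when 1 Mb blocks were shuffled. These 11 included chromosome 1, with 3.79 peaks per Mb before and 5.30 after 153 Mb (block permutation test, adjusted p = 0.0176), but not chromosome 11.

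**Figure D3:**
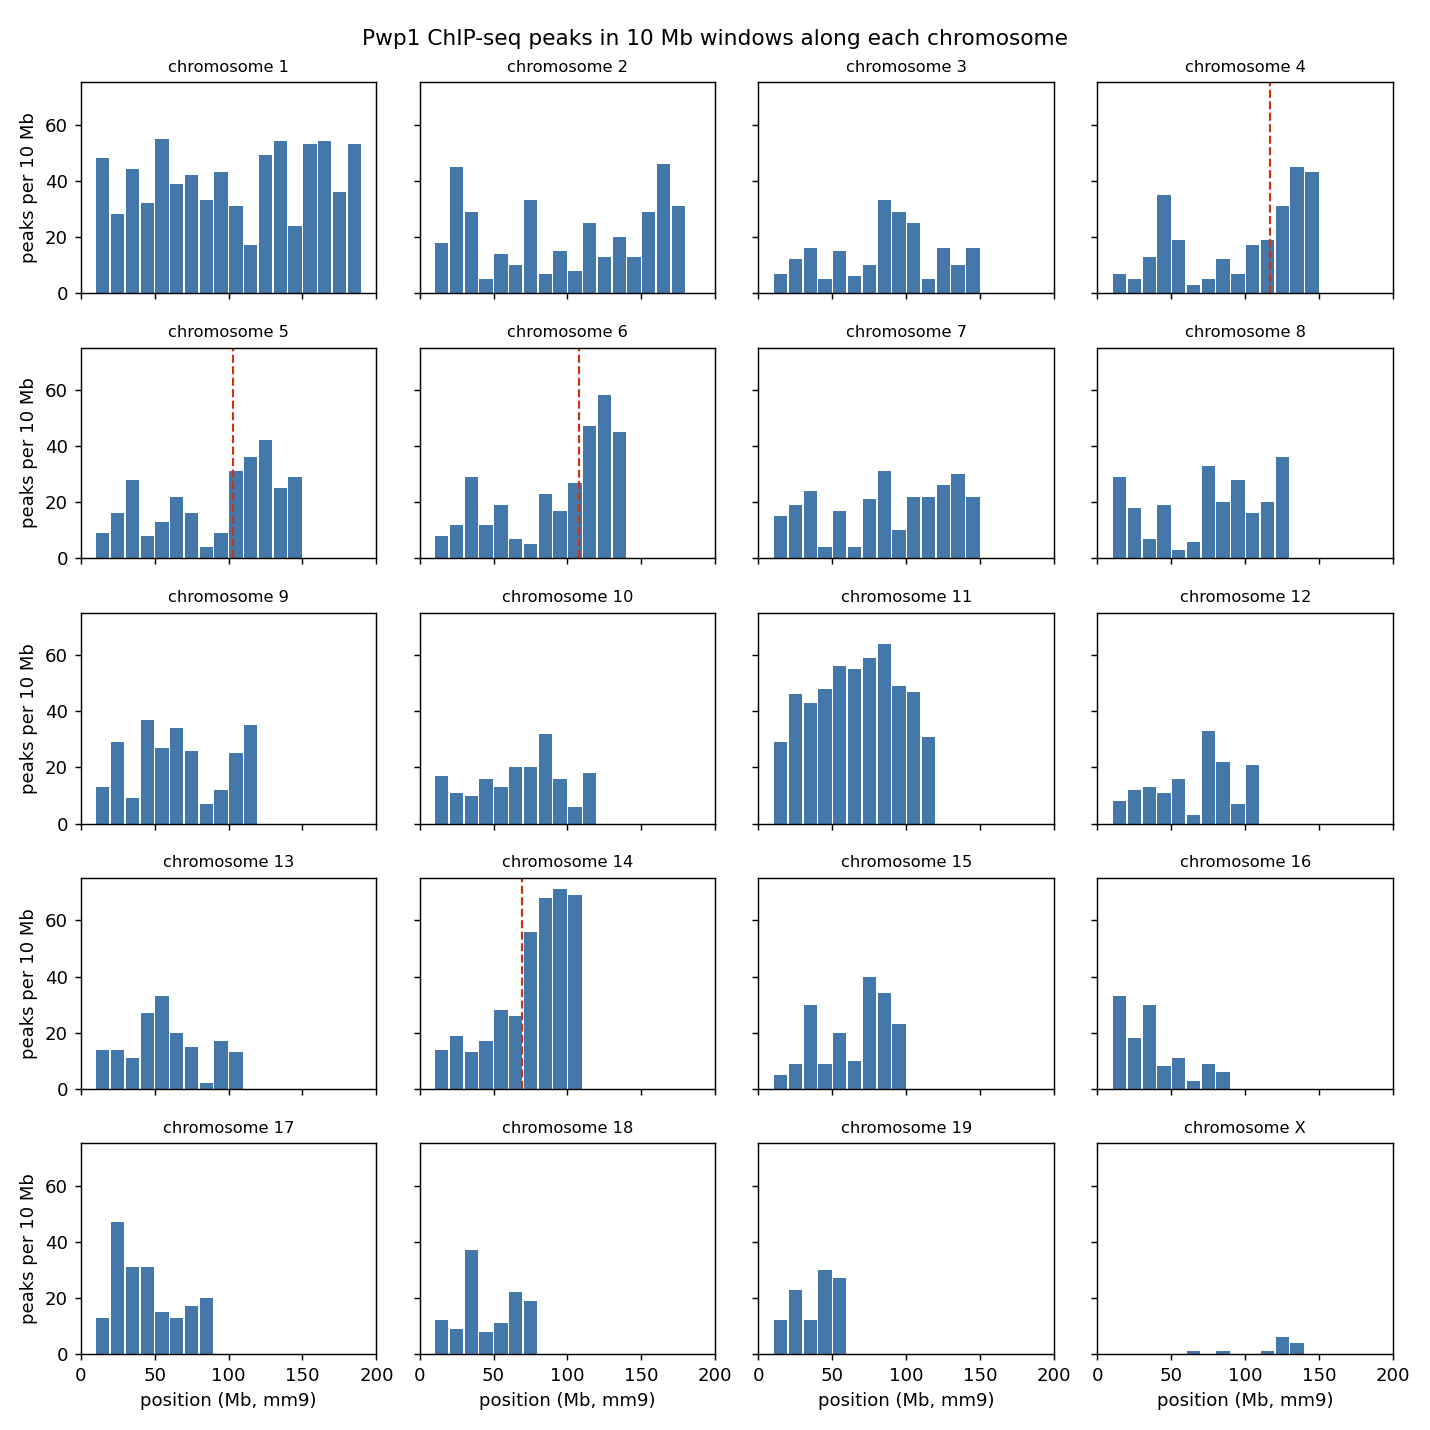
Number of peaks per 10 Mb window (vertical axis) against position in Mb on mm9 (horizontal axis) for each chromosome with a complete window, from the 1 ChIP library. Dashed red lines mark the 4 steps that passed the test, at 117, 103, 108 and 69 Mb on chromosomes 4, 5, 6 and 14, and the windows hold 17 to 55 peaks on chromosome 1 and 29 to 64 on chromosome 11.

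Peaks were also wider on the 3 dense chromosomes. The share of peaks wider than 167 bp was 46.3% on chromosome 11 (95% interval 42.3 to 50.5), 44.1% on chromosome 14 (39.3 to 48.9) and 37.5% on chromosome 1 (34.2 to 41.0). On the other 16 autosomes it averaged 26.8% ± 3.51 (SD over chromosomes), with chromosome 6 highest at 35.4% and the remaining 15 at 30.9% or below. The mean of the 3 dense chromosomes exceeded that of the other autosomes by 15.9 percentage points, the largest difference among the 969 ways of choosing 3 of 19 autosomes (exact permutation test, 2-sided, p = 0.00103). This is the smallest p these splits can give. The 3 chromosomes were taken from the same peak list after densities and widths had been looked at, so it is no independent test. Chromosome 14 was counted whole, although only its distal part was dense, and chromosome 6 was counted among the others. Among the other 16 autosomes density and the share of wider peaks were not significantly related (Pearson r = 0.43, permutation p = 0.101, and Spearman rho = 0.15, permutation p = 0.578, over 1 relation). Without the 2 chromosomes farthest from the median density, r was 0.12. On X, 0 of 17 peaks were wider than 167 bp, which allows a share of up to 17.6% by the limit of 3 counts and of up to 19.5% by the exact interval used for the other chromosomes.

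Wider peaks were also more frequent beyond the steps on chromosomes 6 and 14. On chromosome 14, 25 of 114 peaks (21.9%) before the step and 164 of 315 (52.1%) after it were wider than 167 bp, a difference of 30.1 percentage points (95% interval 20.7 to 39.5; Fisher's exact test, adjusted p = 6.06e-08). On chromosome 6 the share was 25.6% of 160 peaks before and 42.7% of 213 after, a difference of 17.1 points (7.62 to 26.6; Fisher's exact test, adjusted p = 0.00137). On chromosomes 4 and 5 the difference did not pass the test, at 6.27 points (-3.78 to 16.3) and 7.27 points (-2.19 to 16.7), with adjusted p = 0.247 and 0.221 by Fisher's exact test. The steps had been located on the same peaks. These tests and intervals, and those of peak width by Fisher's test or as differences in share further below, treat peaks as independent. Neighbouring peaks may be alike in width, so the p-values can be too small and the intervals too narrow.

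At short range, slightly more peaks had a close neighbour than in random placements. A neighbour within 10 kb was present for 428 peaks, or 7.59%, against 5.30% (95% range 4.47 to 6.15) in random placements over the same chromosome spans (2-sided permutation test by random placement, p = 0.002, the smallest that 1000 placements can give). The excess of 2.29 percentage points fell to 1.37 when peaks within 1 kb were merged (permutation p = 0.004) and to 1.04 when placements stayed inside the 5 Mb window of each peak (permutation p = 0.028). Merging and local placement were not combined. The merged share of 6.65% lay inside the 95% range of the local placements of unmerged peaks (5.75 to 7.41). Clustering beyond split peaks and broad density differences was therefore not shown. Peaks with such a neighbour had no detectable difference in width from the 5211 isolated peaks. The median was 167 bp in both sets, and the means were 170 ± 58.0 bp and 168 ± 50.2 bp (SD over peaks; permutation test of the means, 2-sided, p = 0.529).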

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

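Of 61 recomputed values, 58 kept their direction and their side of the threshold or, for counts, stayed within 1.5 times, and no direction was reversed. Within that limit, the number of chromosomes that differed in density was 4, but 5 with 5 Mb windows, where chromosome 3 passed, and 3 with 20 Mb windows or without X and Y. The number of chromosomes with a density step moved from 4 to 11 when blocks of 1 Mb in place of 5 Mb were shuffled, an alternative added after seeing the data that keeps less of the local unevenness. It remained 4 with 10 Mb blocks, with peaks merged and without peaks of the commonest width. The excess on chromosome 14, 16.8 peaks per 10 Mb window, was 31.4 per 20 Mb window and no longer passed (permutation test, adjusted p = 0.257), where fewer windows were tested. Without 7 X peaks that lie close together, the test of wider peaks on X rests on 10 peaks and did not pass (Fisher's exact test, p = 0.0723). Alternatives that need a value per peak (a stricter threshold, another column of the caller) or a genome were not run. The median width has little power to separate near from isolated peaks, since 30.5% of peaks share 1 width and a moderate shift leaves it at 167 bp. Its difference of 0 has no direction to keep. The fold across a step does not depend on the block size, so there only the p-value could change. The 58 values above include both kinds and overstate stability to that extent. No paired analysis was possible because there is 1 ChIP library. The depth is unknown, and what it limits could not be examined.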

Other observations

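Most tests in this part were chosen after the pattern had been seen in the per-chromosome and per-window counts. The test of occupied bins and that of widths on chromosomes 4 and 5 were set down before their own result was seen.

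Of the 24 peaks on X and Y, 11 were narrower than 75 bp, against 18 of the 5615 autosomal peaks (Fisher's exact test, 2-sided, p = 1.83e-20). On X, 7 of the 17 peaks lay within 2.69 Mb, between 119,944,997 and 122,634,760, and were 61 to 72 bp wide. This group held 7 of the 8 such narrow peaks on X, and without it the count on X and Y was 4 of 17 (Fisher's exact test, 2-sided, p = 4.02e-07). The limit of 75 bp was chosen after the widths were seen. On chromosome 11, the first 4 peaks lay within 68.3 kb and were among the 5 widest of the list. The first peak of the other autosomes had a median width of 167 bp and reached 251 bp at most. Of the 20 widest peaks, 10 lay on chromosome 14 and 8 on chromosome 11. The number of peaks dropped at certain widths, from 75 at 125 bp to 11 at 126 bp and from 36 at 155 bp to 14 at 156 bp.

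The density was high over chromosomes 1 and 11 and over the parts of chromosomes 6 and 14 beyond 108 and 69 Mb, at 4.77 peaks per Mb against 1.85 in the other autosomal sequence. In these segments 96.7% of the 1 Mb bins held a peak (95% interval 94.5 to 98.2), against 69.5% (67.4 to 71.5) elsewhere. This argues against peaks confined to a few local clusters. The segments were chosen by density, which itself raises this share, and the intervals treat neighbouring bins as independent. Whether chromosomes 1 and 11 carry a uniform multiplication of the usual density pattern could not be decided. Counting noise spreads windows with few peaks relatively more, and the bootstrap below treats neighbouring windows of these chromosomes as independent. The lower quartile of 10 Mb windows was 33 peaks on chromosomes 1 and 11 and 10 on the autosomes other than 1, 6, 11 and 14, and the upper quartiles were 53 and 27, so the fold at the lower quartile was 1.68 times that at the upper (bootstrap 95% interval 1.32 to 2.36), while the differences were 23 (19 to 34) and 26 (19 to 31) peaks. A candidate explanation is that the cultured cells carried extra copies of these segments and that peak calling did not remove the added reads. The share of peaks wider than 167 bp was 16.9 percentage points higher there (14.3 to 19.5), and 15.0 points higher (12.5 to 17.5) when the distal parts of chromosomes 4 and 5, whose densities also rose, were counted with these segments. The segments were chosen after densities and widths had been looked at, so this difference had been seen before the explanation was written and is no independent test of it. Extra copies and a preference of Pwp1 for these segments cannot be told apart, since the input library and the gene content were not analysed here, and no biological explanation was tested.

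For the distal parts of chromosomes 4 and 5, a width change as large as the pooled one of chromosomes 6 and 14 is argued against. Whether these parts carry extra copies cannot be decided from it, because a link of peak width to copy number was not tested. Across the steps of chromosomes 4 and 5 the share of wider peaks differed by 6.68 percentage points (95% interval -0.24 to 13.6), against 24.2 (17.6 to 30.8) for chromosomes 6 and 14 pooled. Chromosome 14 carried most of this contrast. The difference for 4 and 5 minus that for 14 was -23.5 points (-35.1 to -11.8), while minus that for 6 alone it was -10.4 (-22.2 to 1.32), so a change of the size on chromosome 6 stays open. The density of genes in these parts was not examined.

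The scarcity of peaks on X may reflect a lower copy number of X than of the autosomes under a fixed peak threshold. The deficit was 14.3-fold, and how large a deficit a lower copy number would give was not examined. On Y, 7 peaks lay within 1.26 Mb, but the peaks themselves set this span and no length of Y was used. Whether peaks were scarce on Y as well could therefore not be judged. The copy numbers of X and Y were not measured here. The peaks on X included 0 of 17 wider than 167 bp, against 26.3% of peaks in the autosomal sequence outside the dense segments (Fisher's exact test, 2-sided, p = 0.0100). Without the group of 7 close peaks it was 0 of 10, which allows up to 30.8% by the exact interval and did not pass (p = 0.0723 by the same exact test). The explanation stays open. A loss of reads from repeated sequence and a true lack of Pwp1 on X were not tested and stay open.

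Of the span of chromosome 11, which carries Stat3, 4.86% lay within 5 kb of a peak, against a median of 1.93% on the 16 autosomes other than 1, 11 and 14. It was 4.06% on chromosome 1 and 3.82% on chromosome 14, so a high share is not particular to chromosome 11 and follows its density. These shares cover all positions and not those of genes, and whether a peak lies at Stat3 was not analysed here.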
